A study of Mus musculus with 9 samples.

How the data were processed

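RNA-seq libraries were made from PT-22 cells, a mouse kidney proximal tubule line whose genotype is given as Pax2-/-, Pax8fl/fl, Rosa-CreERT2 and which carries Pax8 in the inducible vector pTRIPZ. The 9 libraries fall into 3 groups of 3: untreated cells at day 0, cells at day 6 after 1 uM 4-hydroxytamoxifen, and cells at day 12 after subsequent doxycycline at 1 ug/ml. The labels differ on how long 4-hydroxytamoxifen was given, with 2 days in the treatment protocol and 6 days of depletion in the series design. Per the labels' protocols, RNA was polyadenylated RNA extracted with a column kit. The labels do not say whether replicates A, B and C were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Because no vehicle-treated library, no untreated library after day 0 and no doxycycline-free library at day 12 was analysed here, time in culture, each drug and the level of PAX8 change together.

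The authors deposited a table of whole-number counts per gene, not normalised, and a table of TPM in which each library sums to the same fixed total over all its genes. Per the submitters' processing notes, cutadapt 2.3, FastQC 0.11.8, STAR 2.7.8a, RSEM 1.3.3 and the mouse build GRCm38 were used. The role of each tool, the strand setting of the counting, the annotation release and any filter are not given in the sources used here. If RSEM made the counts, they are estimated counts that were rounded before they were deposited. The TPM that the authors computed were used only as an alternative. Gene positions and types came from GENCODE M21 (Ensembl 96) on GRCm38, in which 55141 of the 55487 gene identifiers were found. A further 4 entries for transgenes (Cre, tdTomato, eGFP, mCherry) were left out of library sizes and tests, and held between 0.00204% and 0.00284% of the counts of a library.

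Library totals ran from 56398623 to 86767334 counts, so that 1 count was worth 0.0115 to 0.0177 CPM (counts scaled to the size of the library). Genes were filtered with filterByExpr by group, which left 16353 genes. Counts were scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood F test, R 4.3.3) in 1 fit of all 9 libraries with a mean per group and 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over all genes tested within a comparison. Genes with an adjusted p under 0.05 are said to have risen or fallen. The SE of a log2 fold change is the one implied by the F statistic, and CPM values are TMM-normalised means ± SD of 3 libraries. That SE can be too small where a group holds very few counts, and is left out for Slc6a18. A gene counted as recovered when it differed between day 6 and day 0 and then moved the opposite way between day 12 and day 6. It counted as not recovered when it still differed from day 0 in the same direction at day 12, so a gene that came back part of the way counts as both. Genes changed only after doxycycline differed at day 12 from both earlier groups in the same direction, without a call between day 6 and day 0.

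Before the data were examined, 28 gene lists were fixed, together with the main tests, the alternatives and the rule for naming genes. They cover reported PAX2/PAX8-regulated genes, renal transcription factors, proximal tubule transporters, endocytosis and enzymes, tubule injury, cell cycle, p53 targets, extracellular matrix and mesenchymal transition, epithelial junctions and type I interferon response. Others hold ATF4 targets, mitochondrially encoded proteins, nuclear-encoded oxidative phosphorylation, cholesterol synthesis, fatty acid oxidation, NRF2 targets, hypoxia and glycolysis, NF-kB and inflammatory mediators, Notch, Wnt and YAP/TAZ targets. Markers of loop and distal tubule, collecting duct, podocyte, stromal, endothelial and immune cells complete the set. Lists were tested with camera (limma 3.58.1, two-sided, preset correlation of 0.01, adjusted over the lists of a comparison), and again with an estimated correlation and with fry. The recovered share of a list was set against that of all other genes with Fisher's exact test, adjusted over 25 lists; this comparison was added after the data had been seen.

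Named genes are Pax8 and Pax2, the 6 with the largest change in each direction (adjusted p under 0.05, mean CPM of 5 or more in the higher group, no overlap between libraries, no model names), and up to 3 members with the smallest adjusted p of each called list or 2 of each other list. Further named genes are the 5 in each direction with the largest change among those recovered, not recovered or changed only after doxycycline. Some genes that the rule gave are not reported here. Any other gene named was chosen after its values were seen, as were Malat1, Rpph1 and Neat1. Of the 155 genes that the rule gave, 7 share exon bases with another gene on the same strand (among them L1cam, Parp14, Ndufb2, mt-Co3, mt-Nd4l and mt-Nd1). In all, 36 do so with a gene on the other strand (among them Pax8, Enpp2, Klhl14, Maf, Cftr, Homer2, Cxcl10, mt-Co1 and Kcnq1ot1). Without a stated strand setting, reads of such partners cannot be told apart. Values for members of families with close copies, such as chemokines, Ly6 genes, Saa3, Gstm1 and the mitochondrial genes with nuclear copies, are uncertain where the counting could split reads between copies.

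The procedure was tested on simulated counts for the comparison of day 6 with day 0, drawn for 16353 genes from the means and library sizes of the real libraries with 200 genes changed. At planted folds of 1.2, 1.5, 2 and 4, it called 26, 37, 40 and 44 of 50 genes. The pass criterion set first, that nearly all genes planted at 2-fold or more be called, was not met by these counts. It was then restricted to genes with a mean of at least 1 CPM, of which 38 of 38 were called at 2-fold and 38 of 38 at 4-fold. At 1.2-fold and 1.5-fold, 26 and 36 of 38 such genes were called. Of 16153 unchanged genes, 15 were called in the comparison of day 6 with day 0, and a planted list was called together with 1 unchanged list. Of the 25 genes per fold planted to stay changed, 0 were called as recovered by edgeR, and of the 25 per fold planted to return, 10, 17, 23 and 21 were called as recovered at 1.2-, 1.5-, 2- and 4-fold. Only 200 genes were changed here, whereas 64.9% of genes were called between the real day 6 and day 0 libraries. These rates need not hold there.

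Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma on log2(TPM + 1), no filter and a filter of 5 CPM in all libraries of a group. Others were fits of only the 6 libraries compared, the replicate letter as a block, thresholds of an adjusted p of 0.01 or a fold of 2, and each library left out in turn. Fits of only nuclear protein-coding genes and of TPM rescaled by TMM were added after seeing the data. Also chosen after seeing the data were 31 gene families and annotation classes, tested with camera. The definition of the complement family at first took in unrelated genes and was narrowed after its result had been seen. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 5.22 to 41.4), so each library counted as 1 sample. Ratios for genes with 1 to 3 counts in a group carry an exact 95% interval, which covers counting error only.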

Results

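The 9 libraries held 56398623 to 86767334 counts and 21213 to 22139 detected genes each. In a principal component analysis, the first component took 67.9% of the variance and set the 3 day 0 libraries apart from the other 6. The second took 14.7% and separated day 6 from day 12. Libraries of 1 group correlated across genes at r between 0.9936 and 0.9949. Day 0 libraries correlated with day 6 at 0.9584 to 0.9605, day 0 with day 12 at 0.9658 to 0.9689, and day 6 with day 12 at 0.983 to 0.9878. Genes are not independent replicates, and these values describe the libraries only.

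The targeted gene came first, as a check of the labels. Pax8 (ENSMUSG00000026976, GRCm38 chromosome 2, 24420560 to 24475599, minus strand), a transcription factor of kidney and thyroid development, did not fall in the libraries labelled as depleted. It stood at 291 ± 1.7 CPM at day 0, 405 ± 5.9 at day 6 and 496 ± 7.8 at day 12 (SD, n = 3 each). The log2 fold change was 0.48 ± 0.029 (SE) for day 6 against day 0 (adjusted p = 8.68e-10) and 0.29 ± 0.029 for day 12 against day 6 (adjusted p = 1.22e-06). Its paralog Pax2 (ENSMUSG00000004231, chromosome 19, 44756045 to 44837871, plus strand), given as deleted in the genotype, had 31.9 ± 2.4, 46.9 ± 3.2 and 52.3 ± 3.2 CPM (log2 fold change 0.56 ± 0.06 for day 6 against day 0, adjusted p = 8.64e-07). A count over a whole gene cannot check a deletion whose exons the labels do not name, and endogenous and vector-borne Pax8 reads share it. The groups are therefore called by their day and treatment, and no direction below is a measured response to PAX8 level.

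**Figure D1:**
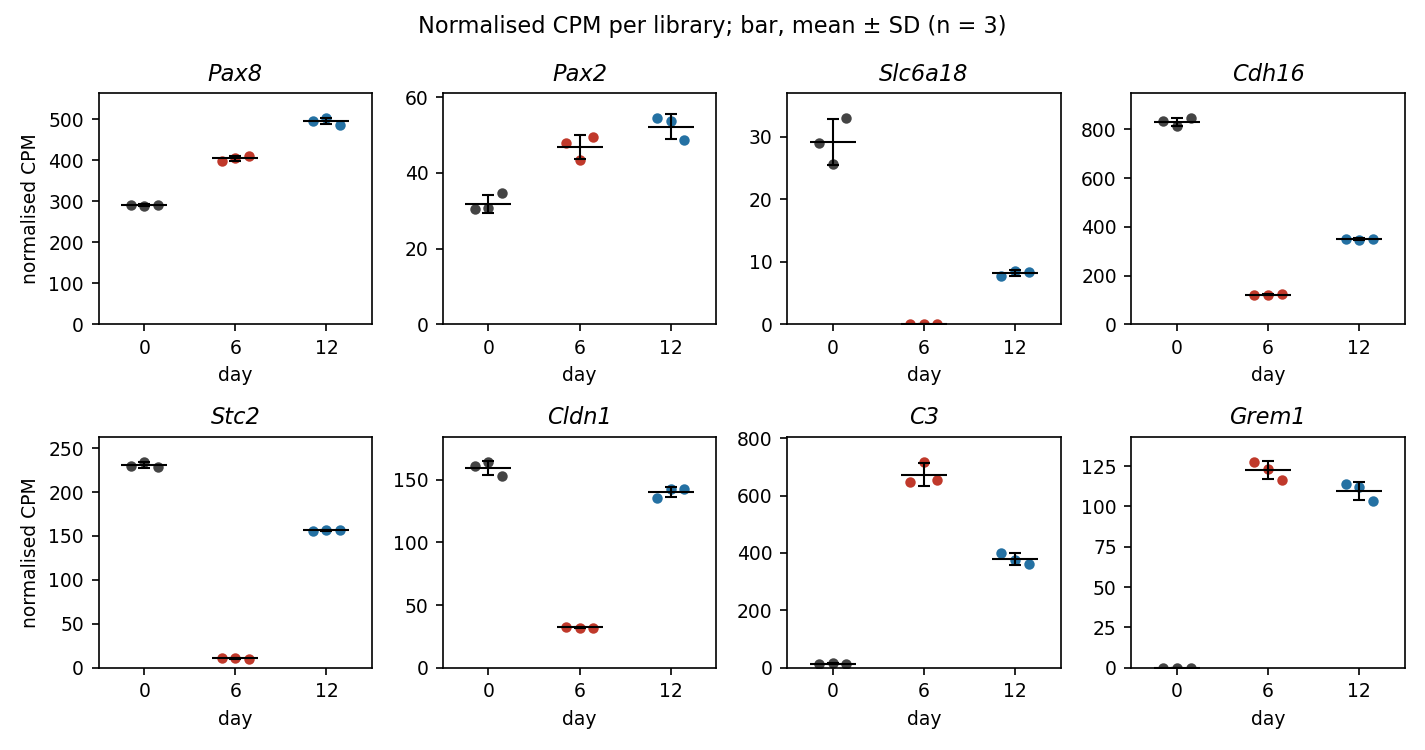
Normalised CPM (y axis, linear from 0) of 8 genes by day (x axis), with 1 point per library and the mean ± SD of 3 libraries as bars. The means of Pax8 and Pax2 were higher at each later day, though the Pax2 libraries of day 6 and day 12 overlapped. Slc6a18, Cdh16, Stc2 and Cldn1 were lowest at day 6, and C3 and Grem1 were lowest at day 0.

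The comparison of day 6 after 4-hydroxytamoxifen with untreated day 0 cells asks what followed the treatment meant to remove PAX8. Slc6a18, a neutral amino acid transporter of the proximal tubule brush border, fell from 29.2 ± 3.7 to 0.041 ± 0.045 CPM (log2 fold change −9.45, adjusted p = 1.04e-14). Its day 6 level rests on very few counts, so the size of this fold is uncertain. Ms4a2, Kcnj16 (a potassium channel subunit), Adgra1, Klhl14 and Cpn1 fell by 64.7-fold to 324-fold. Grem1, a secreted BMP antagonist, rose from 0.0264 ± 0.023 to 122 ± 5.6 CPM, and Enpp2, which makes lysophosphatidic acid, from 0.43 ± 0.078 to 215 ± 15. Ly6d rose 713-fold. Saa3, an acute-phase protein, had 2 counts at day 0 and 3493 at day 6 (ratio 1880, 95% interval 521 to 15600). The vasopressin receptor gene Avpr1a had 2 and 2558 (1380, 382 to 11400), and Mgp 1 and 1100 (1190, 213 to 46900). In total 5472 genes rose and 5133 fell, 64.9% of those tested, and 1579 and 761 did so by at least 2-fold.

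Inflammatory mediators rose as a group. Of 46 tested members of the NF-kB list, 41 rose and 3 fell, with a median log2 fold change of 2.18 (camera, adjusted p = 4.4e-44, and adjusted p = 0.0304 with an estimated correlation). C1s1, a complement protease, rose from 21.8 ± 0.58 to 234 ± 12 CPM. Cxcl5, a neutrophil chemokine, rose from 2.88 ± 0.29 to 83.3 ± 3.5, and Tnfaip3, a feedback inhibitor of NF-kB, from 20.6 ± 0.38 to 125 ± 1.4. Wnt ligands and targets rose in 19 of 27 and fell in 5 (adjusted p = 1.2e-06, and 0.0304 as adjusted p with an estimated correlation). Among them were Wnt10a, at 10.8 ± 0.19 and 55.3 ± 1.9 CPM, and Fzd7, at 38.9 ± 0.96 and 105 ± 2.

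A further 5 lists were called higher with the preset correlation only. Such calls alone are weak, since splits that mixed the groups also gave called lists. Type I interferon response genes rose in 32 of 48 and fell in 8 (adjusted p = 0.00102, and adjusted p = 0.465 with an estimated correlation). Gbp2 was up 4.05-fold and Parp14 2.65-fold. Tubule injury markers rose in 27 of 48 and fell in 17 (adjusted p = 0.000795, estimated correlation adjusted p = 0.0737). Complement C3 stood at 14.4 ± 0.69 and 673 ± 39 CPM and the monocyte chemokine gene Ccl2 at 4.56 ± 0.25 and 142 ± 12. Targets of p53 rose in 29 of 40 and fell in 6 (adjusted p = 0.000102, estimated correlation adjusted p = 0.0737). Trp53inp1 was up 3.69-fold and the death receptor gene Fas 45.7-fold. Matrix and mesenchymal genes rose in 42 of 65 and fell in 18 (adjusted p = 0.000111, estimated correlation adjusted p = 0.0798), with Postn up 31.6-fold and the smooth muscle actin gene Acta2 25.7-fold. Renal transcription factors rose in 12 of 24 and fell in 8 (adjusted p = 0.000433, estimated correlation adjusted p = 0.25), among them Maf (10.4-fold), Mecom (7.93-fold) and Eya1 (4.27-fold).

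Proliferation genes fell almost throughout, in 53 of 60 (median log2 fold change −0.75, adjusted p = 3.66e-20, and adjusted p = 0.0581 with an estimated correlation). Ccnb1, the mitotic cyclin, went from 148 ± 2.5 to 68.5 ± 1.6 CPM, and Cdc20 and the kinetochore motor Cenpe fell 2.08-fold and 2.37-fold. Cholesterol synthesis genes fell in 23 of 26 (adjusted p = 1.19e-09, estimated correlation adjusted p = 0.161), with Hmgcs1 down 2.2-fold. ATF4 targets fell in 32 of 42 (adjusted p = 5.33e-13, estimated correlation adjusted p = 0.0737), among them Asns, which makes asparagine, and the amino acid transporter gene Slc7a5. Nuclear-encoded oxidative phosphorylation genes fell in 48 of 75, by a median of −0.17 on the log2 scale (adjusted p = 0.00794, estimated correlation adjusted p = 0.611), with cytochrome c, Cycs, at 114 ± 1.2 and 64.4 ± 1.9 CPM.

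Of 14 reported PAX-regulated genes, 8 fell and 4 rose (adjusted p = 0.00794, estimated correlation adjusted p = 0.0737). Cdh16, a kidney-specific cadherin, went from 831 ± 16 to 122 ± 2.6 CPM, Cdh6 from 947 ± 27 to 242 ± 0.31 and Npnt from 465 ± 3.6 to 278 ± 8.2. Epithelial junction genes fell in 22 of 44 and rose in 13 (adjusted p = 0.00243, estimated correlation adjusted p = 0.0581), with the tight junction gene Cldn1 at 159 ± 5.7 and 32.2 ± 0.55 CPM. Podocyte and parietal markers fell in 8 of 12 (adjusted p = 0.00857, estimated correlation adjusted p = 0.0737), including Synpo, an actin-binding protein, and Nes. Genes of the proximal tubule did not move 1 way. Of 34 transporters 13 rose and 12 fell (adjusted p = 0.412), 6 endocytosis genes rose and 8 of 16 fell (0.962), and 15 enzymes rose and 11 of 28 fell (0.488, median 0.185 but mean −0.466). The other lists were not called either, with 3 risen and 1 fallen of 13 mitochondrially encoded (adjusted p = 0.962), 22 and 8 of 40 fatty acid oxidation (0.0983) and 16 and 19 of 41 NRF2 genes (0.962). Hypoxia genes rose in 20 and fell in 9 of 41 (adjusted p = 0.216), Notch in 11 and 8 of 23 (0.166) and YAP/TAZ in 14 and 7 of 23 (0.373). Markers of loop and distal tubule (1 and 1 of 6, adjusted p = 0.335), collecting duct (2 and 6 of 8, 0.0606), stroma (8 and 3 of 12, 0.0983), endothelium (6 and 1 of 8, 0.103) and immune cells (2 and 2 of 5, 0.924) stood likewise.

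Adjusted over the list alone, the counts were identical in 22 of the 28 lists and differed by at most 1 gene in the other 6. Median, mean and test had the same sign in each of the 14 called lists and parted in 4 of the others (tubule enzymes, NRF2, loop and immune markers). No vehicle-treated or untreated day 6 library was analysed, so drug, recombination and time cannot be separated here.

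**Figure D2:**
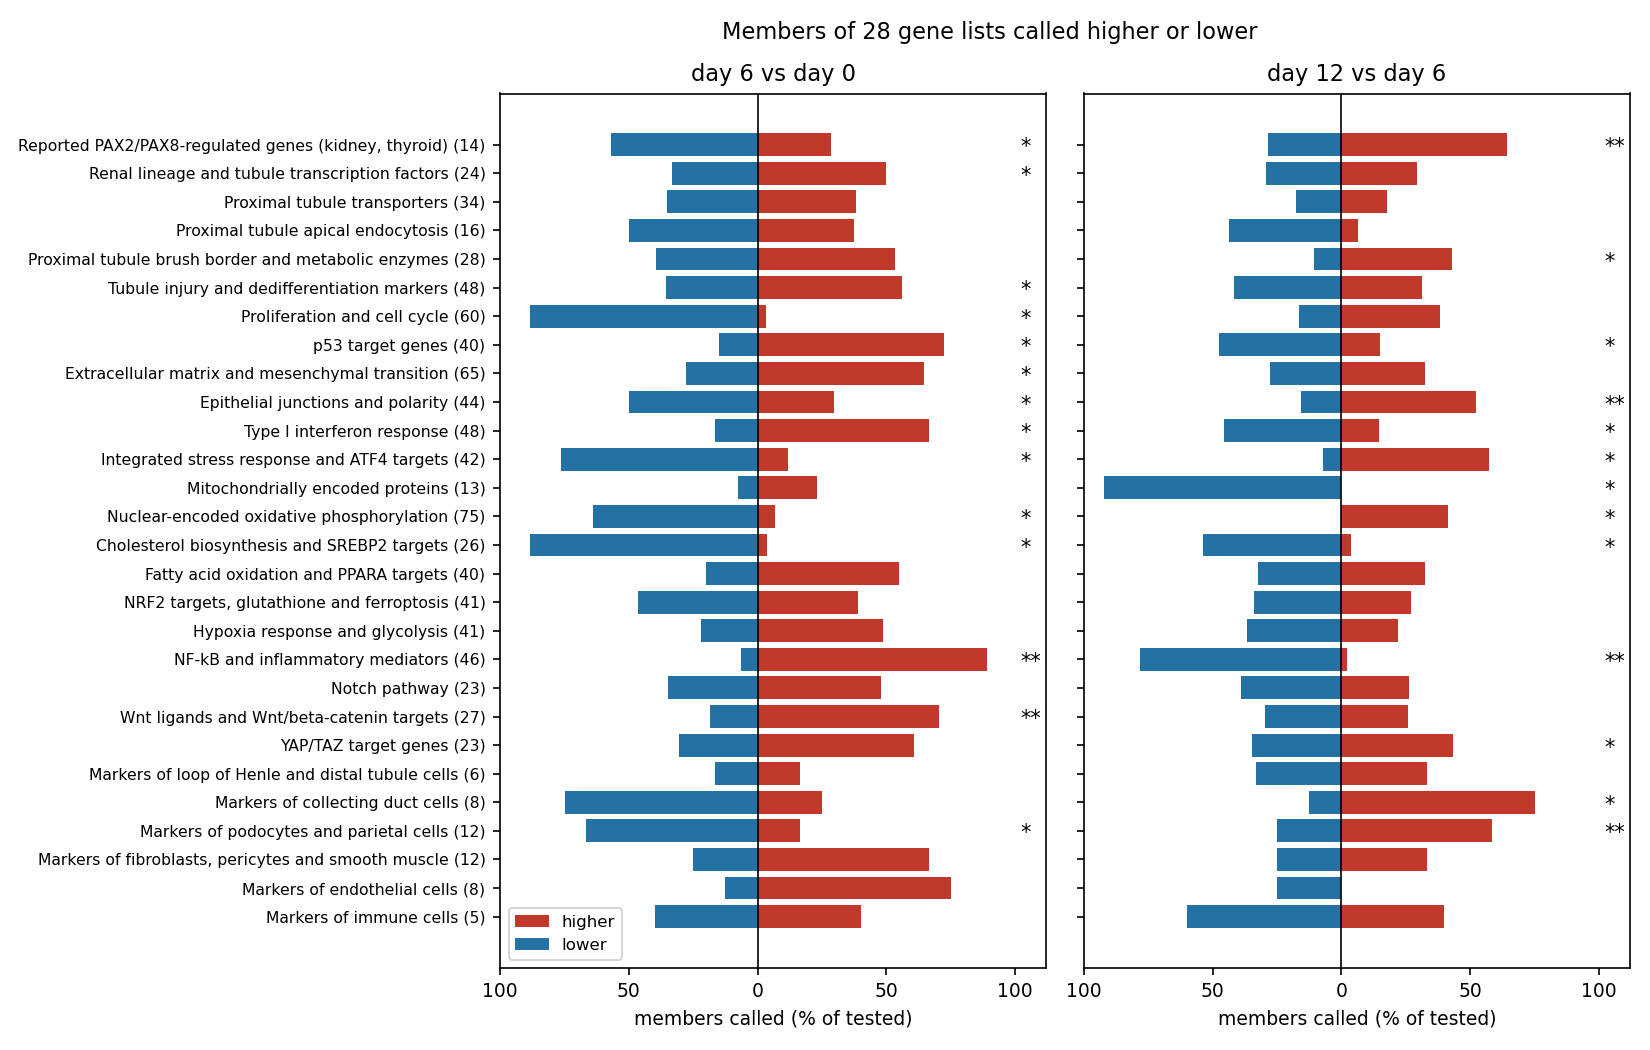
Share of the tested members of each of 28 lists (number tested in parentheses) that were called higher (right, red) or lower (left, blue), in percent of members, for day 6 against day 0 and day 12 against day 6. A single star marks lists called by camera with the preset correlation and a double star those also called with an estimated correlation; 41 of 46 inflammatory genes rose at day 6 and 36 fell at day 12.

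The comparison of day 12 after doxycycline with day 6 asks what followed induction of the Pax8 vector. Many of the genes lowest at day 6 rose. Stc2, a secreted glycoprotein of phosphate and calcium handling, went from 11 ± 0.38 to 156 ± 0.93 CPM (log2 fold change 3.83 ± 0.035, adjusted p = 2.7e-18). L1cam went from 5.57 ± 0.61 to 75.7 ± 2.8, Slc6a18 from 0.041 ± 0.045 to 8.18 ± 0.45 and Klhl14 from 0.182 ± 0.038 to 15.2 ± 0.52. The chemokine gene Ccl5 fell from 61.3 ± 4 to 10 ± 1.6 CPM, Ly6d 4.83-fold, Saa3 4.45-fold and Ch25h, a cholesterol hydroxylase, 3.6-fold. In all, 3702 genes rose and 3706 fell, 45.3% of those tested, of which 373 and 325 moved by at least 2-fold. The share of calls that were higher, 50%, depended on the scaling: it was 60.5% with upper-quartile factors and 91.3% on log2(TPM + 1), where the median of all genes sat at 0.2 (0.0084 with TMM).

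PAX-regulated genes rose in 9 of 14 and fell in 4 (camera, adjusted p = 1.1e-06, and adjusted p = 0.0164 with an estimated correlation). Cdh16 stood at 349 ± 3.6 CPM, up 2.87-fold. Lhx1, a regulator of early nephrons, stood at 23.5 ± 2 after 3.76 ± 0.36. Npnt, of the same list, fell 1.11-fold. Epithelial junction genes rose in 23 of 44 and fell in 7 (adjusted p = 4.29e-06, estimated correlation adjusted p = 0.0164), with Cldn1 back at 140 ± 4.3 CPM and Cdh3 up 1.52-fold. Podocyte and parietal markers rose in 7 of 12 and fell in 3 (adjusted p = 2.22e-06, estimated correlation adjusted p = 0.0164). Synpo, among those that rose, stood at 306 ± 11 CPM. Inflammatory mediators fell in 36 of 46 (median −0.48, adjusted p = 2.91e-20, estimated correlation adjusted p = 0.0388), with Cxcl5 down 3.55-fold, while C3 remained at 379 ± 21 CPM.

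ATF4 targets rose in 24 of 42 (adjusted p = 8.81e-13, estimated correlation adjusted p = 0.0875). Slc3a2, the heavy chain of amino acid transporters, stood at 171 ± 2.7 and 278 ± 6 CPM and the transcription factor gene Atf3 up 2.04-fold. YAP/TAZ targets rose in 10 of 23 and fell in 8 (adjusted p = 0.0123, estimated correlation adjusted p = 0.0875), with Ccn1 up 2.44-fold and Ccn2 1.75-fold. Collecting duct markers rose in 6 of 8 (adjusted p = 0.00927, estimated correlation adjusted p = 0.0875), including Car2. Interferon response genes fell in 22 of 48 and rose in 7 (adjusted p = 0.00367, estimated correlation adjusted p = 0.646). Rsad2 was down 2.34-fold and Cxcl10 2.01-fold. Cholesterol genes fell further, in 14 of 26 (adjusted p = 4.29e-06, estimated correlation adjusted p = 0.33), Insig1 by 1.52-fold. Proximal tubule enzymes rose in 12 of 28 (adjusted p = 0.0367, estimated correlation adjusted p = 0.33), among them the vitamin D hydroxylase gene Cyp27b1. Without day 12 replicate B the adjusted p was 0.0581. Targets of p53 fell in 19 of 40 and rose in 6 (adjusted p = 0.0432, estimated correlation adjusted p = 0.33). The call was lost without day 6 replicate A or B (0.0644 and 0.0731) and without day 12 replicate A, B or C (0.0642, 0.0581 and 0.0542), each left out alone.

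Transcripts of the mitochondrial genome fell in 12 of 13 protein-coding genes (median log2 fold change −1.36, adjusted p = 2.22e-06, estimated correlation adjusted p = 0.33). The oxidase subunit mt-Co1 fell most, from 22800 ± 160 to 5800 ± 2700 CPM (log2 fold change −1.97 ± 0.21, adjusted p = 2.52e-06), whereas mt-Co3 changed by −0.29 ± 0.055 and mt-Nd3 by 0.089 ± 0.062 (adjusted p = 0.267). The mitochondrial share of counts was 6.79% ± 0.14 at day 0, 7.1% ± 0.0737 at day 6 and 2.83% ± 0.992 at day 12, where replicate B stood apart at 3.96% beside 2.43% and 2.1%. On TPM the share was 20.8% ± 0.76, 20.1% ± 0.173 and 12.8% ± 1.92, a smaller fall. Nuclear-encoded oxidative phosphorylation genes rose in 31 of 75, by a median of 0.076 (adjusted p = 0.0176, estimated correlation adjusted p = 0.7). Structural RNAs fell in 8 of 11 (median −1.21, adjusted p = 0.0151, estimated correlation adjusted p = 0.539), after 8 of 11 had risen by day 6 (median 0.915, adjusted p = 0.576). Intron-derived gene models fell in 175 of 553 (median −0.533, adjusted p = 0.00211, estimated correlation adjusted p = 0.539), and the nuclear RNA Malat1 went from 1920 ± 470 to 664 ± 120 CPM. Rpph1 stood at 1.64 ± 0.36, 5.27 ± 3.2 and 2.65 ± 0.9 CPM at the 3 days (log2 fold change −0.98 for day 12 against day 6, adjusted p = 0.0242), whereas the nuclear RNA Neat1 was not called (143 ± 27 and 137 ± 25 CPM, adjusted p = 0.72).

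**Figure D3:**
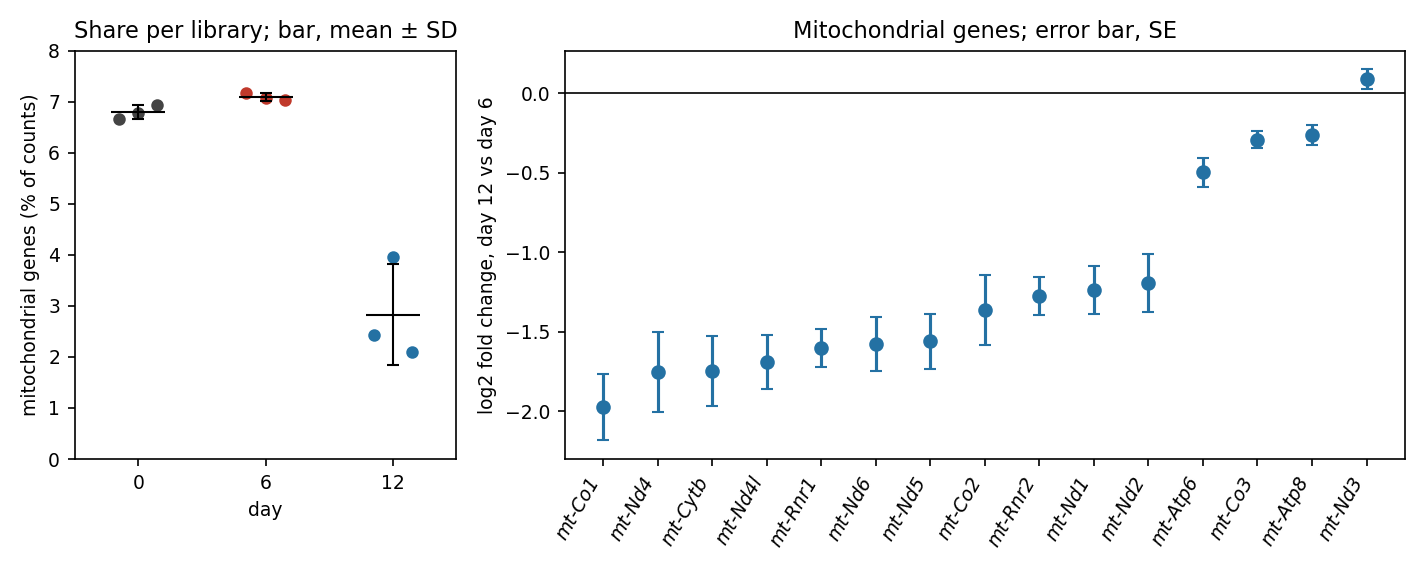
Left, mitochondrial genes as a percentage of all counts (y axis from 0) in each library by day, with the mean ± SD of 3 libraries; right, log2 fold change of each mitochondrial gene between day 12 and day 6, with its SE. The day 12 libraries lie between 2.1% and 3.96%, and the genes range from −1.97 for mt-Co1 to 0.089 for mt-Nd3.

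The remaining lists were not called between day 12 and day 6. Cell cycle genes rose in 23 and fell in 10 of 60 (adjusted p = 0.0932), matrix genes in 21 and 18 of 65 (0.273) and injury markers in 15 and 20 of 48 (0.693). Renal transcription factors did so in 7 and 7 of 24 (adjusted p = 0.928), transporters in 6 and 6 of 34 (0.377) and endocytosis genes in 1 and 7 of 16 (0.32). Fatty acid oxidation stood at 13 and 13 of 40 (adjusted p = 0.697), NRF2 at 11 and 14 of 41 (0.928), hypoxia at 9 and 15 of 41 (0.697), Notch at 6 and 9 of 23 (0.509) and Wnt at 7 and 8 of 27 (0.63). Loop markers had 2 and 2 of 6 (adjusted p = 0.928), stromal 4 and 3 of 12 (0.448) and immune 2 and 3 of 5 (0.928), and 2 of 8 endothelial markers fell (0.427). Adjusted over the list alone, counts were identical in 16 lists and differed by at most 3 genes in 12. Median, mean and test had the same sign in the 13 called lists and parted in 10 of the other 15. Day 12 has no doxycycline-free partner, so doxycycline itself, time and induced Pax8 cannot be separated.

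The comparison of day 12 with day 0 asks what still differed after doxycycline. Grem1, at 110 ± 5.6 CPM, stayed 3710-fold above day 0, Enpp2 322-fold, Ltbp2 279-fold and Serpind1, heparin cofactor, 313-fold. The size of the Grem1 ratio is uncertain, because it rests on very few counts at day 0. On the other side, Adgra1 remained 12.9-fold below, Ms4a2 11.5-fold, Cntn2 8.34-fold, the chloride channel gene Cftr 6.9-fold and Homer2 6.49-fold. A total of 5675 genes were higher and 5186 lower, 66.4% of those tested, and 1542 and 683 differed by at least 2-fold. The higher share of calls was 52.3%, and 81.6% on log2(TPM + 1), where the median of all genes was 0.23.

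Inflammatory mediators were higher in 42 of 46 (camera, adjusted p = 7.41e-33, and adjusted p = 0.0406 with an estimated correlation) and Wnt genes in 21 of 27 (1.81e-09, and adjusted p = 0.0164 with an estimated correlation). Called higher with the preset correlation only were injury markers (27 of 48, adjusted p = 1.68e-05, estimated correlation adjusted p = 0.0543), matrix genes (41 of 65, 2.92e-07 and 0.0691) and p53 targets (26 of 40, 0.000565 and 0.0981). So were renal transcription factors (14 of 24, adjusted p = 2.01e-05, estimated correlation adjusted p = 0.274), interferon genes (28 of 48, 0.03 and 0.599), YAP/TAZ targets (15 of 23, 0.024 and 0.118) and stromal markers (7 of 12, 0.0196 and 0.244). Members also went the other way: 17 injury, 18 matrix, 8 p53, 7 renal transcription factor, 8 interferon, 6 YAP/TAZ and 2 stromal genes were lower. Among the stromal markers, Pdgfrb, a receptor of pericytes and fibroblasts, reached only 1.52 ± 0.29 CPM. Cell cycle genes were lower in 52 of 60 (adjusted p = 1.03e-21, estimated correlation adjusted p = 0.0691), with Ccnb1 at 65.2 ± 1.9 CPM, and cholesterol genes in 23 of 26 (3.5e-21 and 0.0709), with squalene epoxidase, Sqle, at 121 ± 5.3 CPM after 300 ± 7 at day 0. ATF4 targets were lower in 29 of 42 and higher in 9 (adjusted p = 3.43e-06, estimated correlation adjusted p = 0.286). Asns was down 2.19-fold. Mitochondrially encoded genes were lower in 12 of 13 (median −1.18, camera adjusted p = 0.0269, estimated correlation adjusted p = 0.584). Of the TEC and sense intronic models, 195 of 553 were lower and 55 higher (median −0.538, camera adjusted p = 0.0892). Structural RNAs had a median of only −0.283, with 4 of 11 lower (adjusted p = 0.606), and Neat1 was higher (log2 fold change 0.33, adjusted p = 0.0366).

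PAX-regulated genes were not called as a list at day 12 against day 0, with 5 higher and 3 lower of 14 (adjusted p = 0.469), and Cdh16 was still 2.38-fold lower. Junction genes were higher in 17 and lower in 17 of 44 (adjusted p = 0.238), transporters in 11 and 10 of 34 (0.582) and endocytosis genes in 4 and 9 of 16 (0.529). Tubule enzymes were so in 17 and 7 of 28 (adjusted p = 0.0729) and oxidative phosphorylation genes in 11 and 36 of 75 (0.0958). The rest were fatty acid oxidation (24 and 9 of 40, adjusted p = 0.107), NRF2 (15 and 21 of 41, 0.929), hypoxia (18 and 13 of 41, 0.249) and Notch (13 and 7 of 23, 0.252). Nor were markers called of loop (3 and 1 of 6, adjusted p = 0.252), collecting duct (1 and 5 of 8, 0.361), podocyte (3 and 5 of 12, 0.529), endothelial (6 and 1 of 8, 0.187) and immune cells (2 and 3 of 5, 0.808). Adjusted over the list alone, counts were identical in 24 lists and differed by at most 1 gene in 4. Median, mean and test had the same sign in the 13 called lists and parted in 4 others (PAX-regulated genes, transporters, podocyte and immune markers).

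Genes that changed by day 6 were followed to day 12 to ask how far they came back. The median gene regained 15% of its log2 change among those that rose and 24.6% among those that fell, and 10.6% and 39.6% among those moved at least 2-fold. Some came back much further: Klhl14, with 24.4 ± 2.1, 0.182 ± 0.038 and 15.2 ± 0.52 CPM at the 3 days, regained 90.3% of its log2 change, Cldn1 92%, Stc2 87.3% and Slc6a18 80.6%. Ccl5 came back by 39.9%, C3 by 14.9% and Grem1 by 1.3%. The fall of Grem1 after day 6 (log2 fold change −0.16, adjusted p = 0.0107) was not called without day 6 replicate A (0.0658) or day 12 replicate C (0.0598). Of 5472 genes that rose by day 6, 2037 (37.2%) then fell, and of 5133 that fell, 2187 (42.6%) then rose. Among those moved at least 2-fold, it was 583 of 1579 (36.9%) and 510 of 761 (67%). The balance of the 2 directions depended on the scaling. With RLE factors 2082 and 2102 genes recovered, with upper-quartile factors 1715 and 2642, and on log2(TPM + 1) 515 and 3130. A still significant difference from day 0 in the first direction remained for 4397 (80.4%) and 3955 (77.1%), and no difference from day 0 was called for 563 and 730 of the recovered genes. Another 186 and 168 recovered genes had passed day 0 and differed from it the opposite way. Among all genes changed by day 6, 647 and 734 then moved further from day 0. That class overlaps with the genes that still differed. In 20 simulations in which day 12 kept the day 6 means, at most 3 and 2 genes met the definition of recovery. If the calls after day 6 had been independent of the first change, 1240 and 1162 genes would have met it. Both comparisons use the day 6 libraries, with opposite sign, so they are not independent and these figures may be too low. In 20 simulations in which no group differed, this alone gave a mean covariance of −0.023 between the 2 log2 fold changes, against −0.264 observed.

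The share of recovered genes differed between groups. Inflammatory mediators recovered in 34 of 44 changed genes (77.3%, against 39.7% of all others, Fisher's exact test, adjusted p = 1.35e-05), ATF4 targets in 25 of 37 (67.6%, adjusted p = 0.00663), and injury markers in 29 of 44 (65.9%, adjusted p = 0.00463). PAX-regulated genes recovered in 10 of 12 (83.3%, adjusted p = 0.0218), interferon genes in 25 of 40 (62.5%, adjusted p = 0.0218) and junction genes in 22 of 35 (62.9%, adjusted p = 0.0302). The size of the return was smaller than these shares, with a median of 18.7% of the log2 change for inflammatory genes, 17.6% for injury markers and 24.3% for ATF4 targets, near those of all genes. It was 30.3% for junction, 41.4% for interferon and 77.3% for PAX-regulated genes. Cholesterol genes recovered in 1 of 24 (4.17%, adjusted p = 0.00125). Cell cycle genes did so in 23 of 55 (41.8%, adjusted p = 0.933) and matrix genes in 24 of 60 (40%, adjusted p = 1). Genes are not independent of each other within a list, so these p-values describe the lists and not separate experiments. Lists were not matched to the other genes for direction or size of the first change. Of all genes moved at least 2-fold, 67% of those that fell recovered but 36.9% of those that rose. Among changed genes, 32 of 37 ATF4 targets, 22 of 35 junction and 8 of 12 PAX-regulated genes had fallen, while 41 of 44 inflammatory, 32 of 40 interferon and 27 of 44 injury genes had risen.

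A last set changed only after doxycycline, 696 genes upward and 780 downward, but 2140 and 115 on log2(TPM + 1). Prss12, a serine protease, stood at 0.842 ± 0.041, 0.766 ± 0.13 and 5.54 ± 0.24 CPM (log2 fold change 2.86 ± 0.13 for day 12 against day 6, adjusted p = 4.11e-10). Smpd3, a neutral sphingomyelinase, stood at 3.83 ± 0.1, 3.79 ± 0.13 and 12 ± 0.66, and Vav3 at 10.6 ± 0.65, 10.9 ± 0.16 and 18.3 ± 0.48. Downward, the imprinted nuclear RNA Kcnq1ot1 went from 11.4 ± 3.1 at day 6 to 3.59 ± 0.5 CPM, in the same libraries in which the mitochondrial share was lowest.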

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

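The tests of the Pax8 count, of the mitochondrial transcripts and of the reversal at day 12 were chosen only after the results were seen; the counts over other splits of the libraries were planned. The entry for tdTomato, outside the gene tests, had a mean of 2.67 CPM at day 0, 4.2 at day 6 and 5.04 at day 12, and each later library lay above every day 0 library. It drew attention as a signal in data that the comparisons do not use. The labels name no source for this sequence, and none was tested. Cre had 20.4, 17.4 and 20.5 CPM.

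The Pax8 count was higher, not lower, at day 6. The choice among the scalings run was argued against, since the lowest log2 fold change over the settings was 0.456. The scalings differed little here, with medians of all genes between 0.0059 and 0.03 for day 6 against day 0. A shift in total RNA per cell would not show in any of them, and was not tested. Reads from a recombined allele or from the vector could hold the count up, but the effective length implied by counts and TPM moved as much or more in 30.6% of 9994 genes, so this cannot be told apart. Exchanged labels of day 0 and day 6 could also give a rise. The PAX-regulated list was lower at day 6, with an adjusted p of 0.00794 by camera, 1.21e-07 by fry and 0.0737 by camera with an estimated correlation. These values do not decide it, since fry called 25 of the 28 lists in this comparison and camera with the preset correlation is weak alone. The test also takes a fall of PAX8 for granted, which was not measured. An exchange stays open. No biological explanation was tested, because no library separates PAX8 level from time and drug.

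Mitochondrial transcripts were lower at day 12. A few abundant genes shifting the scaling was argued against by the highest median over 3 scalings, −1.32, and an equal loss of mitochondrial RNA of every kind by 11 of the 13 mRNAs, whose level relative to the median of all 13 changed between day 6 and day 12 (limma, 4 higher and 7 lower); a share of reads from nuclear copies was not tested. Fewer RNAs with short or no poly(A) tails entering these libraries may account for it. Structural RNAs had a median of −1.21 and the TEC and sense intronic models of −0.533, but histones of 0.148. At day 12 structural RNAs lay only −0.283 from day 0 (camera, adjusted p = 0.606). Whether TEC models, most of their class, have short tails or none is not given in the sources used here. The classes part, so this cannot be told apart. An effect of doxycycline on mitochondria, of PAX8 or of time stays open and untested.

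Part of the change at day 6 reversed at day 12. The 4224 recovered genes are defined by moving back, so a steady onward drift cannot account for them whatever their number. Simulations without a change after day 6 gave at most 5, which shows only that the reversals exceeded noise. Those simulations held no drift, and changes with time in culture that are not steady were not tested. Changes after day 6 that were unrelated to the first ones would have reversed 1240 and 1162 genes, against 2037 and 2187 observed, so part of the count could arise without any return. Since both comparisons share the day 6 libraries, 1240 and 1162 may be too low. Of the recovered genes, 1288 that had risen and 1289 that had fallen still differed from day 0 in the first direction. They also count among the 8352 not recovered. A further 186 and 168 recovered genes differed from day 0 the opposite way. For the change that remained in these 8352 genes, drift, a lasting effect of 4-hydroxytamoxifen or incomplete restoration cannot be told apart. No untreated later library was analysed. Doxycycline itself could likewise move genes back, and no test here separates it from PAX8.

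With 3 libraries against 3, the 10 splits are too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many genes: 10556 at day 6 against day 0 (highest other 0), 7263 at day 12 against day 6 (highest other 1) and 10684 at day 12 against day 0 (highest other 0). Likewise 1 of 10 gave as many gene lists, with 14, 13 and 13 in the real splits and 8, 5 and 10 as the highest others. The lowest others were 4, 1 and 5 lists, although at most 1 gene was called in any of those splits. Camera with the preset correlation thus called lists where almost no gene differed, so its calls alone are weak. Of 100 splits of the 9 libraries into 3 groups, 2 gave as many recovered genes (4224 in the real one, highest other 7184), 1 as many not recovered (8352, highest other 7175) and 3 as many changed only after doxycycline (1476, highest other 7221), a share under 0.05 for each. Most splits gave 0 by edgeR, and those with higher counts than the real one mixed libraries of different groups, which points to a structure of the samples, so the share says little about chance.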

How the results depend on the processing

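Limma on TPM rescaled by TMM and the fit of nuclear protein-coding genes were tests chosen only after the results were seen. Counts of genes stayed within 1.5 times of those reported under RLE and upper-quartile scaling, DESeq2, both filters, the fits of 6 libraries and the replicate block (letters do not pair the libraries: same-letter deviations correlated at −0.083 to 0.078; with the block 5405 and 5080 genes at day 6 against day 0). On log2(TPM + 1), 7635 genes rose and 727 fell at day 12 against day 6, 1716 were lower at day 12 than day 0, 515 that rose by day 6 recovered, 1507 that fell did not recover, and 2140 and 115 changed only after doxycycline. TPM sum to a fixed total, and rescaling them by TMM gave 2668 and 2816 genes at day 12 against day 6. A fold of at least 2 left 1579 and 761, 373 and 325, and 1542 and 683 genes, since it is a stricter threshold. Required in every comparison used, it left 96 and 239 recovered genes and 1239 and 379 not recovered. Only 57 and 157 changed only after doxycycline at that fold. Lists called numbered 2, 4 and 2 with an estimated correlation and 25, 22 and 26 with fry; fry tests a list without comparing it with other genes. The rise of Pax2 at day 12 against day 6 was narrowly not called by edgeR with RLE scaling (log2 fold change 0.147, adjusted p = 0.0525). It was not called by limma on TMM-scaled TPM either (log2 fold change 0.154, adjusted p = 0.123). Nor was it called by edgeR without day 6 replicate A (adjusted p = 0.064) or B (adjusted p = 0.17) or day 12 replicate A (adjusted p = 0.135) or B (adjusted p = 0.102). Its log2 fold change ran from 0.106 to 0.207 with 1 library left out. The cause was not tested.

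With 1 library left out, counts ran from 5115 to 5540 higher and 4853 to 5200 lower at day 6 against day 0, 3203 to 3728 and 3222 to 3747 at day 12 against day 6, and 5362 to 5704 and 4915 to 5392 at day 12 against day 0. Recovered genes ran from 1741 to 2020 and 1889 to 2175, not recovered from 4130 to 4337 and 3665 to 4006, only after doxycycline from 589 to 713 and 682 to 822, lists from 14 to 15, 11 to 13 and 13 to 13. The log2 fold changes of Pax8 ran from 0.46 to 0.487, 0.281 to 0.305 and 0.756 to 0.781.

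On log2(TPM + 1), 15 named genes changed sign. At day 12 against day 6 these were Grem1 (0.0571), Npnt (0.0573), Slc40a1 (0.0103), Hes6 (0.0827), Apcdd1 (0.0213), Axl (0.0579), Clcn5 (0.0546), Phlda3 (0.0328), Kirrel (0.0269) and Homer2 (0.252; 0.0528 with TMM-scaled TPM). At day 12 against day 0 they were Cldn1 (0.0761), Synpo (0.0057), Cdc45 (0.121), Cdh3 (0.009) and P4ha1 (0.169). The median of all genes moved by a similar amount on this scale, to 0.2 and 0.23; for Homer2, which moved more, the cause was not tested. For named genes other than Pax8 and Pax2, values were compared where the main fit called the gene. Under the other scalings, filters, fits and left-out libraries, 7793 values kept direction and call, 62 lost the call and 16 changed sign. The stricter thresholds are not part of these totals. A total of 71 values are missing, where a gene was not tested in the strict filter, the nuclear protein-coding fit or the fits of TPM. Low counts limit what can be called, as the simulated changes under 1 CPM showed.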

Other observations

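All gene families and annotation classes described here were chosen only after the results were seen. Ly6 genes, which encode small surface proteins anchored by a lipid, rose together at day 6, 8 of 10 (median log2 fold change 3.9, camera, adjusted p = 1.65e-14, and adjusted p = 0.0093 with an estimated correlation). Ly6a stood at 41.7 ± 1.2, 1120 ± 8.7 and 553 ± 18 CPM at the 3 days and Ly6c1 at 0.882 ± 0.15, 113 ± 5 and 37.3 ± 2.1. At day 12 against day 6, 6 of 10 fell (median −0.896, adjusted p = 2.59e-11, estimated correlation adjusted p = 0.00968). Chemokine genes rose in 14 of 15 (median 3.42, adjusted p = 1.17e-18, estimated correlation adjusted p = 0.0159) and fell in 10 of 15 afterwards (median −0.746, adjusted p = 5.34e-12, estimated correlation adjusted p = 0.00968); this family shares members with the inflammatory list. Complement components rose in 8 of 9 (median 2.69, adjusted p = 4.45e-14, estimated correlation adjusted p = 0.0379), and 6 of 9 fell afterwards (median −0.358, adjusted p = 0.00211, estimated correlation adjusted p = 0.276). These medians had the same sign with RLE and upper-quartile factors.

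Claudins, which form tight junctions, rose in 6 of 12 at day 12 against day 6 (median 0.376, adjusted p = 3.79e-06, estimated correlation adjusted p = 0.0451), after 5 had fallen by day 6 (median −0.318, adjusted p = 0.0331, estimated correlation adjusted p = 0.26). Genes of IGF-binding proteins were higher in 4 of 5 at day 12 against day 0 (median 1.37, adjusted p = 0.000153, estimated correlation adjusted p = 0.0372), with Igfbp2 at 11.8 ± 1, 17.8 ± 1.5 and 77 ± 6.6 CPM and Igfbp4 at 0.143 ± 0.034, 11.9 ± 0.79 and 16.3 ± 0.88, while Igfbp5 was lower (118 ± 12, 30.9 ± 1.6 and 32 ± 0.76). Mitochondrial ribosomal protein genes fell in 54 of 78 by day 6 (median −0.194, adjusted p = 0.0187, estimated correlation adjusted p = 0.621) and histone genes in 17 of 35 (median −1.03, adjusted p = 0.0331, estimated correlation adjusted p = 0.479). Many histone messages lack poly(A) tails, and cell cycle genes fell in the same comparison.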
